A study of Mus musculus with 42 samples.

How the data were processed

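ATAC-seq was measured in 42 libraries of sorted mouse microglia in 15 groups of genotype, treatment and surface phenotype. Per the labels, each library pooled cells of 2 to 6 adult male C57BL/6 mice, demyelination was induced with 0.2% cuprizone in the diet, and basal cells were gated as low for CD44, CD45 and CD11b. Flavopiridol and sodium butyrate were in the isolation buffer. The authors trimmed reads with fastp 0.20.0, aligned them with Bowtie2 2.3.4.1 to mm10 (GRCm38) and called and merged peaks with HOMER. They name DESeq2 for their own differential tests, whose results were not used here.

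The deposited count tables hold raw tag counts from HOMER annotatePeaks over merged peaks, in integers, 1 column per library, with the position, annotation class and nearest gene of each peak. The deposited peak lists of the libraries hold positions and a peak score from HOMER findPeaks, called per the file headers at a false discovery rate of 0.001 and 4-fold over the surrounding 10 kb. The count tables used, 5 in all, were those of WT, WT with Trem2KO, basal Cre and Mef2aKO, basal Mef2aKO by CD229, and cuprizone Cre and Mef2aKO. The table of Trem2KO alone was left out, since its header names 9 count columns where its lines hold 8 counts, and its comparisons were made in the joint table. Columns were assigned to samples by the names in the column headers. The 3 WT libraries titled CD229-positive CD11c-positive carry a cell type label that names CD11c-negative cells, and were grouped by title.

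Peaks were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10), scaled with TMM factors of column sums, and tested with the robust quasi-likelihood test of edgeR with all groups of a table in 1 model. A peak passed at a Benjamini-Hochberg adjusted p under 0.05. Group means are CPM with TMM scaling, and SE come from the fit. The biological coefficient of variation was 8.81% in the WT table, 7.70% in the joint table, 9.30% and 4.88% in the basal Mef2aKO tables and 10.4% in the cuprizone Mef2aKO table. Counts of replicates, scaled to the same total, differed by a chi-square per degree of freedom of 1.23 to 2.66. For a fold against a group without counts, 3 counts over the group were set as its bound. The median log2 change of a list moved by up to 0.0713 with such peaks at their bound.

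Before the data were examined, 18 comparisons, 19 lists of 370 genes, the rule for named genes and the alternatives were written down, and 1 interaction was added later. The lists were homeostatic, disease-associated, interferon, NF-kB, cholesterol and lipid, lysosome, antigen presentation and cell cycle genes, Mef2, Sall and Smad factors, AP-1, Mitf and Egr factors, integrin and matrix genes, growth factor genes, and markers of oligodendrocytes, neurons, astrocytes, endothelium, lymphocytes, neutrophils and border macrophages with monocytes. Of the genes 16 stand in more than 1 list. A list was tested over all peaks nearest to its genes with camera of limma 3.58.1, at a correlation between peaks of 0.01 and again at an estimated correlation, with p adjusted over the 19 lists of a comparison. Of 361 list tests 83 passed, and 50 of these with the estimated correlation. Mean, median and direction of the test differed in sign in 72 of 361, none of them among the 83 that passed. Peaks of 1 list lie near the same genes and are not independent, so low p overstate the evidence.

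Named are Trem2, Mef2a, Ly9, Itgax and Clec7a, the 8 higher and 8 lower peaks (3 and 3 in the other comparisons) with the largest fold changes among peaks that passed with separated groups and a mean log2 CPM of at least 2, 1 per gene. Named too are per list the 4 genes with the lowest p and 2 that did not pass. The text gives part of them. After the alternatives were seen, 17 peaks whose call ended under 4 or more of them were taken out of the text, 6 of them in Mef2aKO against Cre CD11c-negative cells, and the tally of alternatives keeps them. Some named genes are not reported here. Main comparisons were CD229-positive against basal and against CD229-negative WT cells, CD11c-positive against CD11c-negative WT cells, Trem2KO against WT CD229-positive cells, and the comparisons of Mef2aKO with Cre in basal, CD11c-negative and CD11c-positive cells.

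The alternatives, 113 fits in all, were DESeq2 1.42.0, RLE factors, column sums without TMM, the tag totals of the peak file headers, cyclic loess offsets, no low-count filter, a minimum count of 30, the compared groups alone, the joint table and replicate numbers as a block. Others were PE150 in library titles as a covariate or left out, libraries with an R2 suffix left out, each library left out in turn, a 2-fold minimum, the fry test, and peaks within 100 kb of their gene. Replicate numbers were checked as pairs by the correlation of deviations from group means. It was higher for the same number in the WT cuprizone subsets (means 0.127 to 0.168, lowest 0.0209) than for others (-0.0834 to -0.0631), but in no pair of groups over 0.1 for every number, so blocks stayed an alternative. With 200 simulated changes added to 5 tables, 43.3% to 53.7% of peaks changed 1.5-fold and 91.0% to 100% of those changed 2-fold were found, with 5 to 9 false calls and 0 in the wrong direction. Motif content and GC corrections were left out, as no genome sequence was at hand. The work used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, R 4.3.3 and bedtools 2.31.1.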

Results

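Open chromatin was measured by ATAC-seq, in which a transposase inserts adapters into accessible DNA, in microglia, the resident macrophages of the brain. The cells were sorted by flow cytometry from adult male C57BL/6 mice, and each of the 42 libraries pooled the brains of 2 to 6 mice of 1 condition. Demyelinating mice had eaten cuprizone, a copper chelator that kills oligodendrocytes, for 4 weeks (wild type, WT, and Trem2 knockout, Trem2KO) or 5 weeks (Cx3cr1CreERT2 control, Cre, and microglial Mef2a knockout, Mef2aKO). Subsets were sorted on the surface proteins CD229, encoded by Ly9, and CD11c, encoded by Itgax. The 5-week cells had also been sorted as positive for Clec7a, a receptor for fungal glucans.

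WT gave 3 basal libraries from healthy mice and 3 libraries each of CD229-negative CD11c-negative, CD229-positive CD11c-negative and CD229-positive CD11c-positive cells from cuprizone-fed mice. Trem2KO gave 2 basal, 3 CD229-negative and 3 CD229-positive CD11c-negative libraries. Cre gave 4 basal, 3 CD11c-negative and 4 CD11c-positive libraries, all of the cuprizone cells being CD229-positive. Mef2aKO gave 2 basal libraries of the whole population, 2 libraries each of basal CD229-negative and basal CD229-positive cells, and 2 CD11c-negative and 3 CD11c-positive libraries from cuprizone-fed mice. Each library held between 15733372 and 49348552 tags, of which 25.4% to 34.4% lay in the library's own peaks. The count tables held between 7490452 and 22287978 counts per library over 146582 to 203941 peaks.

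In the joint table of WT and Trem2KO libraries the first principal component of log CPM held 83.4% of the variance and the second 4.98%. Pairs of replicates had Pearson correlations of log CPM across peaks of 0.936 to 0.975, where peaks are not independent replicates. In the peak sets per library, 91.8% of a library's own peaks on average overlapped a peak of at least 1 other library of its group (86.1% at a reciprocal overlap of 50%, 94.1% for the better-scoring 50%). Signals below are group means of normalised CPM ± SD over the libraries of a group. Log2 fold changes are given ± SE, positions are those of mouse build mm10, and a peak carries the gene whose transcription start site lay nearest. A gene of a list is said to have risen where all of its peaks that passed the test were higher, and to have fallen where all were lower.

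**Figure D1:**
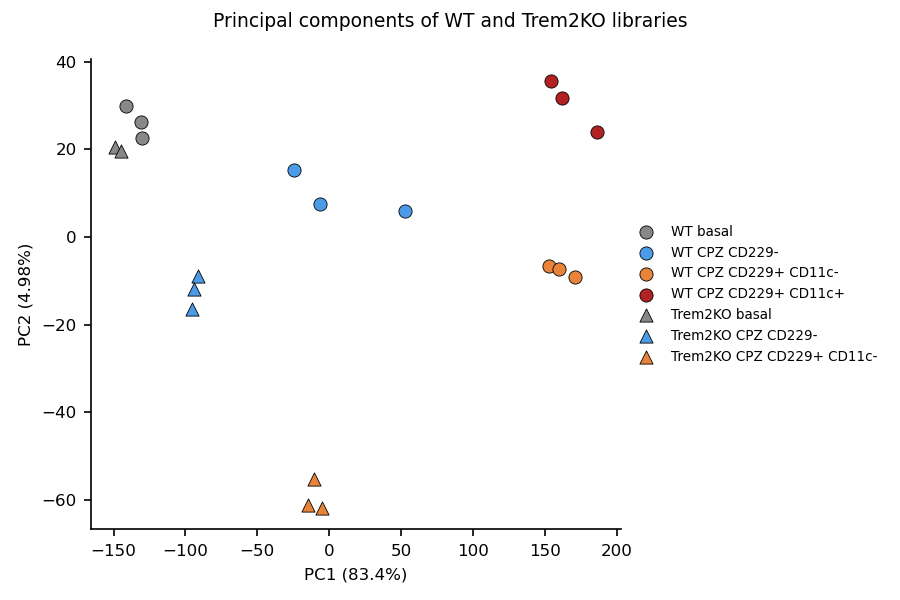
First and second principal components of log CPM for the 20 WT and Trem2KO libraries, each point 1 library, with the axes in units of the component scores. PC1 held 83.4% of the variance.

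The comparison of CD229-positive CD11c-negative cells of cuprizone-fed WT mice with basal WT microglia shows how chromatin differed between these cells and those of the healthy brain (n = 3 in each group). An intergenic peak 139 kb from Igf1, an insulin-like growth factor, rose from 0 counts in the basal libraries to 9.63 ± 1.33 CPM, at least 112-fold (chromosome 10, 87718727 to 87718857). Other peaks without basal counts lay in introns of Dscam, a cell adhesion molecule (11.1 ± 0.847 CPM, at least 130-fold) and of Iqsec1 (8.49 ± 0.467 CPM, at least 99.0-fold). An intronic peak of Pde4d, a cyclic AMP phosphodiesterase, also had no basal counts (8.36 ± 1.24 CPM, at least 97.6-fold). These bounds set 3 counts over the basal group. The deepest losses included a peak at the start of Fosb, an AP-1 subunit, which fell from 16.8 ± 3.71 to 1.50 ± 0.295 CPM (log2 -3.51 ± 0.21). An intronic peak of Trim30d fell from 22.0 ± 1.36 to 1.33 ± 0.602 CPM (log2 -3.99 ± 0.19). The promoter of the orphan receptor gene Gpr165 fell from 45.0 ± 3.98 to 5.58 ± 0.859 CPM (log2 -3.03 ± 0.12).

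Peaks near genes known to be induced in disease-associated microglia rose as a set. Of 30 genes on the list 13 rose, 1 fell, 16 moved both ways and 0 did not pass. Nearest to them were 400 higher and 61 lower of 624 peaks (adjusted p = 5.36e-16, up to 0.0313 over alternatives). Csf1, the ligand of the receptor that keeps microglia alive, rose 6.86-fold (20.8 ± 0.238 against 2.97 ± 0.394 CPM). Ctsb, a lysosomal protease, rose 9.99-fold (18.7 ± 1.13 against 1.89 ± 0.559 CPM). Lpl, which releases fatty acids from lipoproteins, rose 6.96-fold (21.2 ± 1.78 against 3.04 ± 0.29 CPM). The Igf1 promoter rose 10.7-fold (19.2 ± 2.68 against 1.87 ± 0.435 CPM). Of 26 cholesterol and lipid genes 6 rose, 2 fell, 18 moved both ways and 0 did not pass (231 higher and 58 lower of 432 peaks, adjusted p = 1.25e-06). An intronic peak of Acaca, which makes malonyl-CoA for fatty acid synthesis, went from 0.0252 ± 0.0437 to 14.1 ± 0.872 CPM, and a promoter peak of the apolipoprotein gene Apoc1 rose 5.24-fold. Growth factor and cytokine signalling genes moved up as a set, 4 rose, 4 fell, 11 moved both ways and 0 did not pass of 19 (adjusted p = 0.000153). Tnfrsf1b, a receptor for tumour necrosis factor, was 9.15-fold higher and Csf2ra, a receptor chain for GM-CSF, 2.33-fold lower.

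Interferon-response genes rose as a set, 13 rose, 1 fell, 11 moved both ways and 1 did not pass of 26 (adjusted p = 0.00633). They included the Slfn2 promoter (5.55-fold). Integrin, matrix and migration genes also rose as a set, 9 rose, 0 fell, 12 moved both ways and 0 did not pass of 21 (adjusted p = 0.00633). Itga5, a chain of the fibronectin receptor, was 31.7-fold higher, and Itgam, which encodes CD11b, was 10.9-fold higher, while Itgav was 2.45-fold lower. The list of Mef2, Sall, Smad and partner transcription factor genes fell as a set, 0 rose, 2 fell, 14 moved both ways and 0 did not pass of 16. It had 120 higher and 243 lower of 711 peaks (adjusted p = 0.0394, adjusted p = 0.0876 with an estimated correlation, 1.82e-05 to 0.0876 over alternatives). An intronic peak of Mef2c went from 68.2 ± 5.81 to 33.8 ± 1.73 CPM. A peak near Smad7, an inhibitor of TGF-beta signalling, fell 2.66-fold, and a distal Klf4 peak rose 24.1-fold.

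Other lists had peaks moving both ways and did not pass as sets. Of 25 homeostatic microglial genes 1 rose, 3 fell, 21 moved both ways and 0 did not pass (163 higher and 234 lower of 791 peaks, adjusted p = 0.195). Within it a Gpr34 peak fell 2.74-fold, and an intronic peak of Tgfbr2, a TGF-beta receptor, rose 12.4-fold. The list of AP-1, Mitf, Egr and Runx genes had 218 higher and 214 lower of 735 peaks (adjusted p = 0.644). Peaks at the start of Egr1 and Jun, both immediate early genes, fell 4.51-fold (11.1 ± 1.66 against 49.7 ± 2.53 CPM) and 3.20-fold, and an intronic Runx1 peak rose 25.5-fold (23.0 ± 1.55 against 0.991 ± 0.473 CPM). The NF-kB and inflammatory list had 173 higher and 103 lower of 453 peaks (adjusted p = 0.0666), with Tnfaip3, a brake on NF-kB, 24.1-fold higher and the chemokine gene Ccl2 10.0-fold higher. Lysosome and phagocytosis genes had 104 higher and 65 lower of 312 peaks (adjusted p = 0.328), with Lamp1 8.76-fold higher. Antigen presentation genes had 38 higher and 43 lower of 153 peaks (adjusted p = 0.677). The costimulator gene Cd86 was higher (log2 3.59 ± 0.20), and the class II gene H2-Aa was 1.99-fold lower. Cell cycle genes had 67 higher and 39 lower of 183 peaks (adjusted p = 0.195), with a peak 57.5 kb from Mki67 18.5-fold higher.

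Peaks nearest to marker genes of other cell types moved as well. The neutrophil list was higher as a set, with 22 higher and 6 lower of 46 peaks (adjusted p = 0.0211, adjusted p = 0.174 with an estimated correlation, 2.60e-05 to 0.174 over alternatives). It includes Csf3r, the receptor of granulocyte colony-stimulating factor (2.62-fold higher). The counts were 42 higher and 26 lower of 123 (adjusted p = 0.195) for border macrophages and monocytes, 19 higher and 5 lower of 51 (adjusted p = 0.154) for lymphocytes and 55 higher and 30 lower of 141 (adjusted p = 0.161) for endothelium. They were 36 higher and 32 lower of 120 (adjusted p = 0.894) for astrocytes, 7 higher and 10 lower of 48 (adjusted p = 0.637) for neurons and 26 higher and 35 lower of 121 (adjusted p = 0.894) for oligodendrocytes. Single peaks near F13a1, expressed by border macrophages, and Cspg4, which encodes NG2, were 40.3-fold and 96.7-fold higher. In all, 87215 of 164963 peaks passed, 44519 higher and 42696 lower, and 31756 higher and 10204 lower by at least 2-fold. Scaling by column sums alone moved the median of all peaks by 0.21 (log2) and gave 55616 higher and 28536 lower.

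CD229-negative cells of cuprizone-fed WT mice were compared with basal WT cells to show what had changed in the subset without CD229 (n = 3 in each group). The peak 139 kb from Igf1 rose from 0 counts to 1.81 ± 0.591 CPM, at least 21.1-fold. Peaks near Psmc6, a proteasome subunit gene, and Ldlrad3 rose by at least 23.3-fold and at least 22.8-fold. The peak at Fosb fell (4.28 ± 0.814 against 16.8 ± 3.71 CPM, log2 -1.98 ± 0.17). On the disease-associated list 17 rose, 3 fell, 8 moved both ways and 2 did not pass of 30. It had 170 higher and 19 lower of 624 peaks (adjusted p = 2.29e-09, adjusted p = 0.0525 with an estimated correlation, 8.77e-11 to 0.0525 over alternatives). The cholesterol and lipid list (adjusted p = 0.000331), the growth factor list (adjusted p = 0.00817), the interferon list (adjusted p = 0.00844) and the integrin and matrix list (adjusted p = 0.0084) were higher as sets. Of 21 integrin and matrix genes 16 rose, 1 fell, 4 moved both ways and 0 did not pass. Neutrophil markers had 9 higher and 0 lower of 46 peaks (adjusted p = 0.018, adjusted p = 0.132 with an estimated correlation, 0.00151 to 0.299 over alternatives, lost without basal WT replicate 1 at 0.07 and WT CD229-negative replicate 1 at 0.0867). In all, 28515 of 164963 peaks passed, 14996 higher and 13519 lower, and 9744 higher and 238 lower by at least 2-fold. Column sums alone moved the median by 0.14 (log2) and gave 21285 higher and 4813 lower. Cyclic loess offsets gave 11883 higher and 3759 lower, and a fit of both groups alone called 18823 peaks.

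Within the cuprizone-fed WT mice, CD229-positive CD11c-negative cells were compared with CD229-negative cells (n = 3 in each group). A peak 41.6 kb from Mamdc2 rose 8.41-fold (8.63 ± 0.757 against 1.04 ± 0.435 CPM, chromosome 19, 23489846 to 23490027), and the Dscam intron peak rose 8.01-fold (11.1 ± 0.847 against 1.44 ± 0.735 CPM). Intronic peaks of Etl4 and of Nfil3 rose 6.94-fold (16.2 ± 2.40 against 2.36 ± 1.23 CPM) and 6.68-fold (10.7 ± 1.58 against 1.67 ± 1.15 CPM). A peak near Tle3 rose 7.10-fold. Peaks within Trim30d and Rtf2 fell 7.10-fold (1.33 ± 0.602 against 9.78 ± 0.495 CPM) and 6.03-fold (1.66 ± 0.266 against 10.1 ± 1.10 CPM).

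Between these subsets 17 rose, 1 fell, 12 moved both ways and 0 did not pass of 30 disease-associated genes. They had 319 higher and 33 lower of 624 peaks (adjusted p = 4.50e-18, up to 0.0106 over alternatives). The promoter of Apoe, the main lipid carrier of the brain, rose 3.04-fold (17.8 ± 1.19 against 6.00 ± 2.03 CPM). Lpl rose 2.54-fold and the distal Igf1 peak 5.43-fold. Of 26 cholesterol and lipid genes 12 rose, 4 fell, 9 moved both ways and 1 did not pass (adjusted p = 6.79e-07), with Acaca 5.06-fold higher. Growth factor genes were higher as a set (6 rose, 5 fell, 8 moved both ways and 0 did not pass, adjusted p = 2.81e-05). So were integrin and matrix genes (10 rose, 3 fell, 8 moved both ways and 0 did not pass, adjusted p = 0.0279, 4.03e-06 to 0.0573 over alternatives, lost without WT CD229-positive CD11c-negative replicate 1 at 0.0573). Osm, which encodes oncostatin M, was 5.48-fold higher, and Cd44, a hyaluronan receptor, 2.33-fold higher. The interferon list was higher as a set (adjusted p = 0.0235, adjusted p = 0.0689 with an estimated correlation, 0.000108 to 0.0689 over alternatives, lost without WT CD229-positive CD11c-negative replicate 1 at 0.0558). The Mef2, Sall and Smad list was lower as a set, 0 rose, 4 fell, 11 moved both ways and 1 did not pass of 16 (adjusted p = 0.0235, adjusted p = 0.0691 with an estimated correlation, 0.000219 to 0.0691 over alternatives). Smad7 was 2.02-fold lower. P2ry13, a purine receptor of resting microglia, fell 3.71-fold (2.50 ± 0.552 against 9.23 ± 0.775 CPM). Neutrophil markers had 11 higher and 3 lower of 46 peaks, and the list did not pass (adjusted p = 0.0649). In all, 52148 of 164963 peaks passed, 26796 higher and 25352 lower, and 14941 higher and 5140 lower by at least 2-fold.

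CD229-positive CD11c-positive cells of cuprizone-fed WT mice were also compared with basal WT cells (n = 3 in each group). Peaks near Igf1, Pde4d and Iqsec1 had no basal counts and reached 11.9 ± 1.67, 8.21 ± 4.18 and 8.07 ± 0.575 CPM, at least 139-fold, at least 95.8-fold and at least 94.2-fold. Peaks within Rtf2 (0.532 ± 0.264 against 11.9 ± 0.984 CPM) and at Fosb (1.45 ± 0.532 against 16.8 ± 3.71 CPM) fell. Of the 30 disease-associated genes 14 rose, 0 fell, 16 moved both ways and 0 did not pass (adjusted p = 3.66e-18). An Apoe promoter peak rose 8.91-fold. Cholesterol and lipid genes had 225 higher and 47 lower of 432 peaks (adjusted p = 1.18e-07), and growth factor genes 151 higher and 62 lower of 329 peaks (adjusted p = 1.92e-05). Of the homeostatic genes Gpr34 fell 3.76-fold and the promoter of Tmem119, a microglial surface protein, 2.13-fold. Neutrophil markers had 20 higher and 8 lower of 46 peaks (adjusted p = 0.0183, adjusted p = 0.135 with an estimated correlation, 1.46e-05 to 0.163 over alternatives). In all, 86762 of 164963 peaks passed, 44224 higher and 42538 lower, and 31279 higher and 10192 lower by at least 2-fold. Column sums alone moved the median by 0.16 (log2) and gave 52636 higher and 30664 lower.

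CD11c-positive and CD11c-negative cells among the CD229-positive cells of cuprizone-fed WT mice were compared for what went with CD11c (n = 3 in each group). The 3 CD11c-positive libraries are grouped by their titles, as their cell type labels name CD11c-negative cells. Peaks higher in CD11c-positive cells lay in introns of Necab1, a neuronal calcium-binding protein (13.1 ± 1.41 against 3.54 ± 0.567 CPM, log2 1.90 ± 0.20), and Pnoc, the precursor of nociceptin (9.68 ± 1.08 against 2.63 ± 0.652 CPM). Others lay within Dcbld2 (13.7 ± 0.944 against 3.94 ± 0.997 CPM) and near Clec4n, a C-type lectin receptor (10.4 ± 1.19 against 2.97 ± 0.515 CPM). The promoter of Mmp12, macrophage elastase, rose 3.35-fold (9.47 ± 0.367 against 2.84 ± 0.417 CPM). Lower peaks lay near Disp1, which releases Hedgehog proteins (2.61 ± 1.28 against 10.7 ± 1.96 CPM, log2 -2.04 ± 0.33), and Trim33 (1.70 ± 0.734 against 6.22 ± 1.02 CPM). Lower peaks within genes were those of Abcc4, an exporter of cyclic nucleotides (1.83 ± 0.328 against 5.84 ± 1.64 CPM), and Ripk4 (4.02 ± 1.40 against 12.4 ± 0.702 CPM). With DESeq2 the call was lost for Ripk4 (log2 -1.63).

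Of 18 antigen presentation genes 5 rose, 0 fell and 13 did not pass. They had 14 higher and 0 lower of 153 peaks (adjusted p = 7.28e-06, adjusted p = 0.19 with an estimated correlation, 6.21e-08 to 0.19 over alternatives, 21 and 0 adjusted over the list alone). They were led by Ciita, the regulator of class II genes (2.64-fold, 5.89 ± 0.258 against 2.22 ± 0.165 CPM), the costimulator gene Cd80 (3.80-fold) and H2-Aa (1.68-fold). Disease-associated genes went apart, 10 rose, 2 fell, 3 moved both ways and 15 did not pass of 30 (adjusted p = 0.235 for the list). Among them were the promoter of Atp6v0d2, a proton pump subunit (3.55-fold higher), a Csf1 peak (1.56-fold higher) and a peak near Hif1a, the hypoxia factor (2.56-fold lower). Of 26 cholesterol and lipid genes 6 rose, 1 fell, 1 moved both ways and 18 did not pass (adjusted p = 0.363), with Cd36, a scavenger receptor, 2.65-fold and Pparg, a lipid-sensing nuclear receptor, 2.39-fold higher. Of 28 AP-1, Mitf and Egr genes 13 rose, 3 fell, 1 moved both ways and 11 did not pass (adjusted p = 0.0668), with Tfec 2.47-fold and Runx1 3.44-fold higher. NF-kB genes had 12 higher and 6 lower of 453 peaks (adjusted p = 0.0668), including Nfkb1 (2.88-fold higher), Tnfaip3 (2.49-fold higher) and Rel (2.10-fold higher). Interferon genes had 1 higher and 6 lower of 207 peaks (adjusted p = 0.0668), with Zbp1, a nucleic acid sensor, 2.66-fold lower. Integrin and matrix genes had 19 higher and 4 lower of 343 peaks (adjusted p = 0.12), with the promoter of Itga4, an integrin chain, 1.87-fold higher and Itgb3 1.85-fold lower. Peaks near neuronal markers were 6 higher and 0 lower of 48 (adjusted p = 0.0668). Without WT CD229-positive CD11c-negative replicate 2 the call was lost for H2-Aa (log2 0.65), and without WT CD11c-positive replicate 1 for H2-Aa (log2 0.55) and Zbp1 (log2 -1.06).

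In all, 6780 of 164963 peaks passed between these subsets, 3962 higher and 2818 lower, and 1256 higher and 1279 lower by at least 2-fold. The number was 2429 with DESeq2. It was 4178, 3105 and 3957 without WT CD229-positive CD11c-negative replicates 1, 2 and 3 in turn and 3075 and 3136 without WT CD11c-positive replicates 1 and 2 in turn. Column sums alone gave 2956 higher and 3614 lower. The Cre libraries, from other mice after 5 weeks of cuprizone, gave the same contrast (n = 4 and 3). There 3421 of 163482 peaks passed, 1905 higher and 1516 lower. Both tables measured 149078 peaks. Of these 1026 were higher in both, where chance gives 46.1, 764 were lower in both, where chance gives 26.2, and 0 passed in opposite directions. In Cre cells peaks near Tusc1 (7.80 ± 1.04 against 1.89 ± 0.606 CPM) and Gda, guanine deaminase (7.79 ± 1.05 against 2.25 ± 0.421 CPM), rose. The Atp6v0d2 promoter rose 2.87-fold and the Mmp12 promoter 2.68-fold. Peaks near Disp1 (2.72 ± 1.01 against 8.27 ± 2.11 CPM) and within Actr10 (2.08 ± 0.358 against 7.04 ± 1.09 CPM) fell. Antigen presentation genes had 8 higher and 0 lower of 150 peaks in Cre cells (adjusted p = 8.45e-06, adjusted p = 0.214 with an estimated correlation, 2.06e-08 to 0.214 over alternatives). Disease-associated genes had 28 higher and 0 lower of 633 peaks (adjusted p = 0.000111, adjusted p = 0.114 with an estimated correlation, 1.54e-05 to 0.167 over alternatives). Neuronal markers were higher as a set in them (adjusted p = 0.00519, adjusted p = 0.209 with an estimated correlation, 0.000994 to 0.209 over alternatives). The Cre count was 1818 with DESeq2. It was 1747 and 1297 without Cre CD11c-negative replicates 2 and 3 in turn and 2047 without Cre CD11c-positive replicate 2, and 141 without the 4 libraries titled PE150. Without the PE150 libraries the call was lost for Atp6v0d2 (log2 1.10).

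The genes behind the sort markers and the knockouts were followed. In CD229-positive CD11c-negative against basal WT cells the Ly9 promoter rose from 2.37 ± 0.667 to 4.66 ± 1.85 CPM (chromosome 1, 171607286 to 171607414) and an Itgax intron peak from 1.54 ± 0.111 to 5.96 ± 0.222 CPM (chromosome 7, 128138468 to 128138605). A peak 1.93 kb from Clec7a went from 9.56 ± 0.725 to 19.9 ± 1.79 CPM, and the promoter of Trem2, a lipid-sensing receptor, from 7.56 ± 1.06 to 15.5 ± 2.67 CPM. The promoter of Mef2a, a MADS-box transcription factor, fell from 37.0 ± 0.813 to 22.6 ± 1.80 CPM (chromosome 7, 67373166 to 67373260). Without WT CD229-positive CD11c-negative replicate 1 the call was lost for Ly9 (log2 0.61). Between CD11c-positive and CD11c-negative WT cells 0 of 16 Itgax peaks passed by edgeR. In Trem2KO cells the Trem2 promoter peak did not differ past the threshold from WT in the CD229-positive subset (13.5 ± 0.238 against 14.7 ± 2.41 CPM, adjusted p = 0.481), and passed with cyclic loess (log2 -0.30). The Mef2a promoter stood at 33.6 ± 3.39 against 33.9 ± 0.751 CPM in basal Mef2aKO against Cre cells. These peaks need not lie in the deleted parts, which the labels do not give, so they do not test the deletions.

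**Figure D2:**
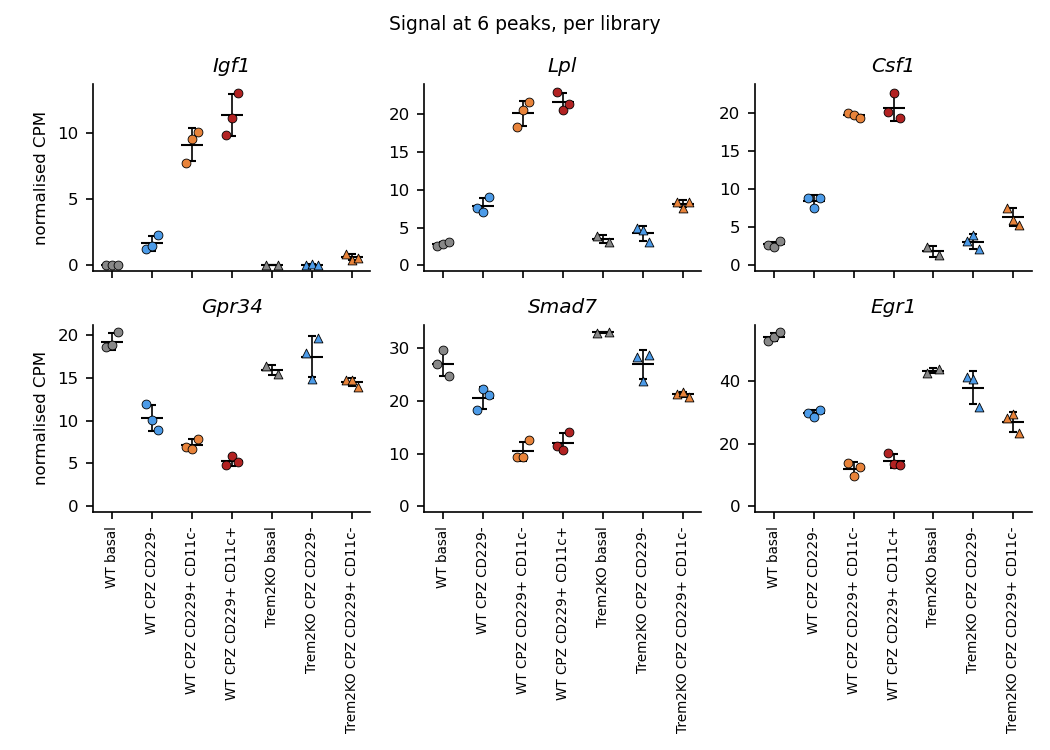
Normalised CPM of 1 peak each near Igf1, Lpl, Csf1, Gpr34, Egr1 and Smad7 in every WT and Trem2KO library (points) with group mean and SD (bars), n = 2 or 3 per group. The Igf1 peak stood at 9.12 ± 1.24 CPM in WT and 0.609 ± 0.231 CPM in Trem2KO CD229-positive CD11c-negative cells.

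Basal Trem2KO microglia (n = 2) were compared with basal WT microglia (n = 3), both from healthy mice, and 32 of 181759 peaks passed, 17 higher and 15 lower. A peak 60.8 kb from Trp53i11 rose (log2 1.19 ± 0.18). A peak within Tank, which binds TRAF proteins (1.53 ± 0.0474 against 4.27 ± 0.718 CPM), fell. Without basal WT replicate 3 the call was lost for Trp53i11 (log2 1.01) and Tank (log2 -1.53), and without basal Trem2KO replicate 1 for Trp53i11 (log2 1.15) and Tank (log2 -1.54). Without basal WT replicate 1 the call was lost for Tank (log2 -1.43), and without basal Trem2KO replicate 2 for Tank (log2 -1.48). No peak of any of the 19 lists passed, and none of the lists did (lowest adjusted p = 0.114). DESeq2 called 25 peaks, and 12547 of 181759 had an unadjusted p under 0.05 in edgeR. The header totals as scaling gave 17 and a fit of both groups alone 178. Leaving out 1 library gave 0 and 16 without basal Trem2KO replicates 1 and 2 in turn and 18, 18 and 3 without basal WT replicates 1, 2 and 3 in turn.

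After 4 weeks of cuprizone, Trem2KO CD229-positive CD11c-negative cells were compared with WT cells of the same gate (n = 3 in each group). An intronic peak of Rfc5 fell from 16.8 ± 1.27 to 0.246 ± 0.128 CPM (log2 -6.04 ± 0.28). A peak within Postn, periostin, fell from 8.64 ± 1.52 to 0.157 ± 0.044 CPM (log2 -5.70 ± 0.30). Peaks 258 kb from Kcnj2, a potassium channel, and within Specc1l fell from 12.2 ± 2.49 to 0.325 ± 0.207 and from 21.2 ± 1.98 to 0.606 ± 0.275 CPM. The distal Igf1 peak fell from 9.12 ± 1.24 to 0.609 ± 0.231 CPM (log2 -3.87 ± 0.24). Peaks 60.8 kb from Trp53i11 (6.85 ± 0.543 against 0.627 ± 0.339 CPM, log2 3.48 ± 0.25) and within Rtf2 (14.6 ± 0.376 against 1.60 ± 0.229 CPM, chromosome 2, 172430714 to 172430843) were higher in Trem2KO cells. So were peaks within Tppp (14.5 ± 0.853 against 2.28 ± 0.726 CPM) and Hk1, a hexokinase (4.09 ± 0.41 against 0.662 ± 0.279 CPM).

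In Trem2KO 0 rose, 9 fell, 21 moved both ways and 0 did not pass of 30 disease-associated genes. They had 50 higher and 332 lower of 678 peaks (adjusted p = 4.17e-14, up to 0.00657 over alternatives). Dkk2, a Wnt antagonist, fell 8.44-fold (1.34 ± 0.17 against 11.4 ± 0.528 CPM), Ank 8.71-fold and Mamdc2 8.71-fold. Of 26 cholesterol and lipid genes 4 rose, 6 fell, 15 moved both ways and 1 did not pass (adjusted p = 0.00426). They included Acaca (10.5-fold lower, 1.39 ± 0.112 against 14.8 ± 1.30 CPM), Lpl (2.46-fold lower) and Ch25h, cholesterol 25-hydroxylase (3.44-fold lower). Growth factor genes were lower as a set (4 rose, 4 fell, 11 moved both ways and 0 did not pass of 19, adjusted p = 0.00514). So were integrin and matrix genes (1 rose, 9 fell, 11 moved both ways and 0 did not pass of 21, adjusted p = 0.028, 2.56e-08 to 0.0553 over alternatives, lost without WT CD229-positive CD11c-negative replicate 1 at 0.0553). Peaks in these lists included Pdgfa at 0.0711 ± 0.0794 against 3.13 ± 0.205 CPM, Osm 10.9-fold lower and the promoter of Fn1, fibronectin, 7.20-fold lower. Of 25 homeostatic genes 5 rose, 0 fell, 20 moved both ways and 0 did not pass. The list was higher as a set (adjusted p = 0.0447, adjusted p = 0.0655 with an estimated correlation, 0.000183 to 0.0932 over alternatives, lost without WT CD229-positive CD11c-negative replicates 1 and 2 at 0.055 and 0.0511). The Crybb1 promoter rose 2.85-fold (12.6 ± 2.53 against 4.44 ± 0.746 CPM) and Gpr34 2.03-fold, while Tgfbr2 fell 5.78-fold. Among transcription factor genes, whose 172 higher and 85 lower of 788 peaks did not pass as a set (adjusted p = 0.0558), a distal Klf4 peak fell from 6.75 ± 0.367 to 0.298 ± 0.0975 CPM and Maf rose 1.86-fold. Egr1 rose 2.26-fold and Runx2 fell 10.1-fold. Endothelial markers had 12 higher and 48 lower of 162 peaks (adjusted p = 0.00514), led by Flt1 (7.90-fold lower).

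In all, 59556 of 181759 peaks passed, 29307 higher and 30249 lower, and 3474 higher and 17903 lower by at least 2-fold. Of 31061 peaks that were higher by at least 2-fold in WT CD11c-positive than in basal WT cells, none of whose libraries are compared here, 63.9% were lower in Trem2KO (median log2 -0.91), and of 10158 that were lower in WT 47.0% were higher (median 0.57). Of 10000 peaks that did not respond in WT, at the level of the former, 8.36% were lower and 4.87% higher. Across all peaks the change from basal in Trem2KO had a slope on that in WT of 0.497 (CD229-positive) and 0.340 (CD229-negative). Per library it was 0.451 ± 0.0159 and 0.274 ± 0.0172 (SD, 3 Trem2KO libraries). Noise in the WT change lowers slopes, so they are not shares of response kept. Cyclic loess offsets called 38243 peaks. Column sums alone gave 18793 higher and 38305 lower (median shift -0.12, log2), and header totals 37001 and 23383 (0.12).

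**Figure D3:**
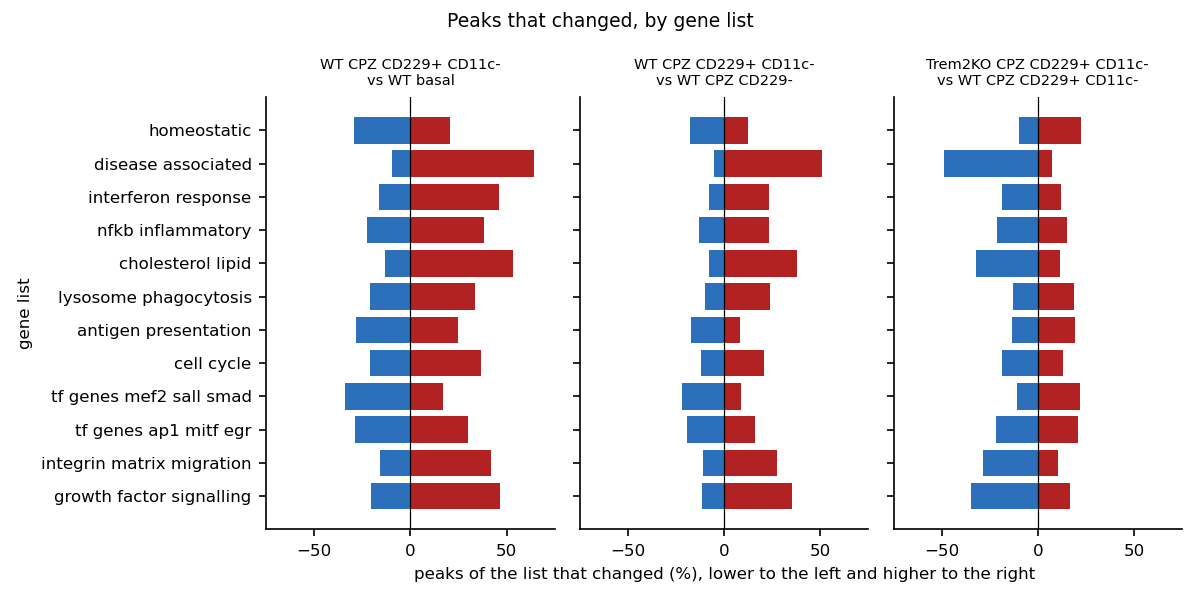
Share of each gene list's peaks that were lower (left) or higher (right) in 3 comparisons, with 12 lists of genes on the vertical axis and percent on the horizontal axis. Of the 678 peaks near disease-associated genes 332 were lower and 50 higher in Trem2KO than in WT CD229-positive CD11c-negative cells.

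In the CD229-negative subset Trem2KO cells (n = 3) had 14612 of 181759 peaks that differed from WT (n = 3), 7338 higher and 7274 lower, and 117 higher and 4873 lower by at least 2-fold. Peaks near Specc1l (0.192 ± 0.0895 against 5.39 ± 2.97 CPM) and Kcnj2 (0.0982 ± 0.0483 against 2.75 ± 1.51 CPM) fell. Intronic peaks of Cryz, a quinone reductase (7.81 ± 1.80 against 3.19 ± 0.726 CPM), and Eepd1 (10.1 ± 0.0656 against 4.34 ± 1.06 CPM) rose. Disease-associated genes were lower as a set, 3 rose, 13 fell, 8 moved both ways and 6 did not pass of 30 (adjusted p = 1.36e-09), with Csf1 2.78-fold lower and the Bhlhe40 promoter 2.31-fold lower. Growth factor genes had 19 higher and 49 lower of 355 peaks (adjusted p = 0.0143), and the cholesterol and lipid list was lower too (adjusted p = 0.0143, 0.000605 to 0.0566 over alternatives, lost without WT CD229-negative replicate 3 at 0.0566). Homeostatic genes had 46 higher and 11 lower of 888 peaks (adjusted p = 0.0405, 0.00285 to 0.192 over alternatives, lost without WT CD229-negative replicate 3 at 0.192 and Trem2KO CD229-negative replicate 1 at 0.0569). The Crybb1 promoter was 1.83-fold higher. Endothelial markers had 3 higher and 12 lower of 162 peaks (adjusted p = 0.0405, 0.000776 to 0.249 over alternatives, lost without any 1 library other than WT CD229-negative replicate 1 and Trem2KO CD229-negative replicate 3 at 0.0557 to 0.083). Also lower as sets were neuronal markers, with 0 higher and 1 lower of 53 peaks (adjusted p = 0.0405, 0.00228 to 0.106 over alternatives, lost without WT CD229-negative replicate 3 at 0.0714 and Trem2KO CD229-negative replicate 1 at 0.0814), and neutrophil markers, with 1 higher and 5 lower of 49 peaks (adjusted p = 0.0405, adjusted p = 0.0563 with an estimated correlation, 0.00143 to 0.157 over alternatives, lost without any 1 library other than WT CD229-negative replicate 2 and Trem2KO CD229-negative replicate 3 at 0.0589 to 0.15). The count was 8312 by DESeq2, 4270 fitting both groups alone and 7670 without both R2 libraries. It was 9224 and 9105 without Trem2KO CD229-negative replicates 1 and 3 in turn. Column sums alone gave 1677 higher and 9661 lower with a median shift of -0.11, cyclic loess 1129 higher and 4612 lower and header totals 3500 higher and 6161 lower.

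An interaction term tested whether the change from basal to CD229-positive CD11c-negative cells differed between Trem2KO and WT, and 20619 of 181759 peaks passed, 13798 higher and 6821 lower. The Rfc5 peak went from 0.0466 ± 0.0808 to 16.8 ± 1.27 CPM in WT and from 0.0979 ± 0.138 to 0.246 ± 0.128 CPM in Trem2KO (difference of log2 changes -6.98 ± 1.79). The Fosb peak went from 15.7 ± 3.32 to 1.42 ± 0.279 CPM in WT and from 9.04 ± 2.63 to 4.24 ± 0.284 CPM in Trem2KO (2.38 ± 0.29). Without basal Trem2KO replicate 2 the call was lost for Rfc5 (log2 -3.12). Disease-associated genes had a lower change in Trem2KO as a set, with 19 higher and 56 lower of 678 peaks (adjusted p = 0.00559, adjusted p = 0.274 with an estimated correlation, 0.000524 to 0.274 over alternatives). The count was 12702 and 13360 without basal Trem2KO replicates 1 and 2 in turn. Cyclic loess gave 3950 higher and 5193 lower, and column sums alone 7208 higher and 9165 lower with a median shift of -0.13.

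Within Trem2KO, CD229-negative cells differed from basal cells (n = 2) at 985 peaks, 887 higher and 98 lower, and CD229-positive cells at 40003, 22581 higher and 17422 lower. The Apoe promoter rose from 2.11 ± 0.064 in basal to 6.77 ± 0.945 and 18.5 ± 2.70 CPM, and an intronic Runx1 peak from 0.442 ± 0.391 to 3.36 ± 0.572 and 14.6 ± 0.373 CPM. In CD229-positive cells 232 higher and 25 lower of 678 peaks near disease-associated genes passed (adjusted p = 2.17e-11). So did 136 higher and 19 lower of 454 peaks near cholesterol genes (adjusted p = 1.30e-07) and 12 higher and 0 lower of 49 peaks near neutrophil markers (adjusted p = 0.00166). Lymphocyte markers were higher as a set there (adjusted p = 0.0108). CD229-positive against CD229-negative Trem2KO cells gave 24903 peaks, 14493 higher and 10410 lower, with Apoe 2.76-fold higher and a Crim1 peak at 2.43 ± 0.776 against 6.93 ± 0.767 CPM. Between these subsets markers of neutrophils (adjusted p = 0.000497), lymphocytes (adjusted p = 0.00595) and border macrophages and monocytes (adjusted p = 0.0289, 4.51e-06 to 0.0909 over alternatives, lost without Trem2KO CD229-negative replicate 1 at 0.0533 and Trem2KO CD229-positive replicate 3 at 0.0637) were higher as sets. Those of oligodendrocytes (adjusted p = 0.00867) and neurons (adjusted p = 0.0153) were lower, and the NF-kB list was higher (adjusted p = 0.00281, adjusted p = 0.0982 with an estimated correlation, 9.00e-05 to 0.0982 over alternatives, lost without Trem2KO CD229-negative replicate 3 at 0.0524). The 3 counts became 610, 28734 and 15815 with DESeq2. Leaving out 1 library moved the first to 250 and 121 without basal Trem2KO replicates 1 and 2 in turn, and the second to 22674 and 18663 without basal Trem2KO replicates 1 and 2 in turn. The third was 15882 without Trem2KO CD229-positive replicate 3. Without the R2 libraries the third was 9917, and header totals gave 636 for the first and 17571 higher and 2764 lower for the third.

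Basal microglia of Mef2aKO mice (n = 2) were compared with basal Cre microglia (n = 4). A peak 114 kb from E030018B13Rik stood at 27.4 ± 4.92 against 0.0969 ± 0.0537 CPM (log2 8.09 ± 0.25, chromosome 7, 63802921 to 63803003). Higher peaks also lay near Prpf18 (11.1 ± 0.802 against 0.204 ± 0.103 CPM, chromosome 2, 4616841 to 4616929). Peaks within Blvrb, biliverdin reductase (10.6 ± 2.89 against 0.405 ± 0.222 CPM) and near Cd48, a ligand of SLAM family receptors (9.27 ± 3.18 against 1.15 ± 0.38 CPM) were higher. An intronic peak of Cyfip1 fell from 8.87 ± 1.24 to 1.63 ± 0.159 CPM (log2 -2.44 ± 0.21, chromosome 7, 55870568 to 55870643). The promoter of Atp10a fell from 9.80 ± 2.01 to 2.18 ± 0.784 CPM, and a peak near Socs6 from 23.3 ± 4.81 to 5.60 ± 2.43 CPM. Of the peaks that differed by at least 2-fold, 168 lay within 170 to 180 Mb of chromosome 1, 15.7% of the peaks tested there. On chromosome 7 89 lay within 20 to 70 Mb, 3.11% (and 16.1% from 50 to 60 Mb), against 0.639% on the other chromosomes. Bins on chromosomes 9 (110 to 120 Mb), 16 (40 to 50 Mb) and 2 (0 to 10 Mb, with Prpf18) held 2.95%, 4.51% and 2.23%. The peaks of E030018B13Rik, Blvrb, Cd48, Cyfip1 and Atp10a lie in the segments of chromosomes 1 and 7, as do Mef2a and Ly9. Without basal Cre replicate 4 the call was lost for Socs6 (log2 -2.07).

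Of 25 homeostatic genes 2 rose, 10 fell, 1 moved both ways and 12 did not pass (adjusted p = 0.855 for the list), with Tgfbr2 2.60-fold lower (2.22 ± 0.75 against 5.73 ± 0.578 CPM) and Gpr34 1.67-fold lower. Among 30 disease-associated genes 8 rose, 4 fell and 18 did not pass (adjusted p = 0.939), among them Cd9, a tetraspanin (1.84-fold lower), Cd63, a lysosomal tetraspanin (2.10-fold higher), and the chemokine gene Ccl3 (2.08-fold higher). NF-kB genes were higher as a set, 7 rose, 2 fell and 15 did not pass of 24 (adjusted p = 0.00458, adjusted p = 0.153 with an estimated correlation, 0.000573 to 0.153 over alternatives). The promoter of Tnf, tumour necrosis factor, was 1.50-fold and Tlr2, a receptor for bacterial lipoproteins, 1.88-fold higher. Antigen presentation genes were also higher, 3 rose, 0 fell and 15 did not pass of 18 (adjusted p = 0.00297, adjusted p = 0.0869 with an estimated correlation, 0.00115 to 0.0869 over alternatives). The Cd80 promoter was 1.86-fold higher. AP-1, Mitf and Egr genes were higher as a set, 6 rose, 2 fell and 20 did not pass of 28 (adjusted p = 0.0234, adjusted p = 0.113 with an estimated correlation, 0.0107 to 0.113 over alternatives, lost without basal Cre replicates 1 and 4 at 0.0609 and 0.0804 and basal Mef2aKO replicate 2 at 0.11). Integrin and matrix genes had 6 higher and 2 lower of 283 peaks (adjusted p = 0.0493, adjusted p = 0.0869 with an estimated correlation, 0.0128 to 0.11 over alternatives, lost without any 1 library at 0.0516 to 0.11). Growth factor genes had 4 higher and 0 lower of 262 peaks (adjusted p = 0.0499, adjusted p = 0.113 with an estimated correlation, 0.0155 to 0.287 over alternatives, lost without any 1 library other than basal Mef2aKO replicate 1 at 0.0629 to 0.287). Mitf, a regulator of lysosomal genes, fell 1.63-fold, and Ifnar1, an interferon receptor chain, rose 2.28-fold. Neuronal markers were lower as a set, with 0 higher and 5 lower of 44 peaks (adjusted p = 0.0206, adjusted p = 0.153 with an estimated correlation, 0.00347 to 0.843 over alternatives, lost without basal Cre replicates 1 and 2 at 0.107 and 0.0546 and basal Mef2aKO replicate 2 at 0.171), and higher without passing at peaks within 100 kb of their gene. Astrocyte markers were lower too, with 2 higher and 4 lower of 102 peaks (adjusted p = 0.0206, adjusted p = 0.153 with an estimated correlation, 0.00594 to 0.153 over alternatives, lost without basal Cre replicate 3 at 0.0651 and basal Mef2aKO replicate 2 at 0.11). Among them were peaks far from Syt1 (2.69-fold lower) and Slc1a3 (3.03-fold lower). A peak 53.0 kb from Mef2a, in the chromosome 7 segment, rose 1.63-fold. Without basal Mef2aKO replicate 2 the call was lost for Cd63 (log2 0.78), Tnf (log2 0.54), Cd80 (log2 0.95) and Ifnar1 (log2 0.56), and with header totals for Tnf (log2 0.53). Without basal Mef2aKO replicate 1 the call was lost for Tnf (log2 0.62), Tlr2 (log2 0.90) and Cd80 (log2 0.85), and with replicate blocks for Tlr2 (log2 0.75) and Cd80 (log2 0.78). With DESeq2 the call was lost for Tlr2 (log2 0.92) and Cd80 (log2 0.90).

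In all, 3013 of 143465 peaks passed, 956 higher and 2057 lower, and 271 higher and 890 lower by at least 2-fold. The number was 1149 with DESeq2, 1591 with replicate blocks, 1112 and 1617 without basal Mef2aKO replicates 1 and 2 in turn, and the header totals gave 418 higher and 1847 lower.

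**Figure D4:**
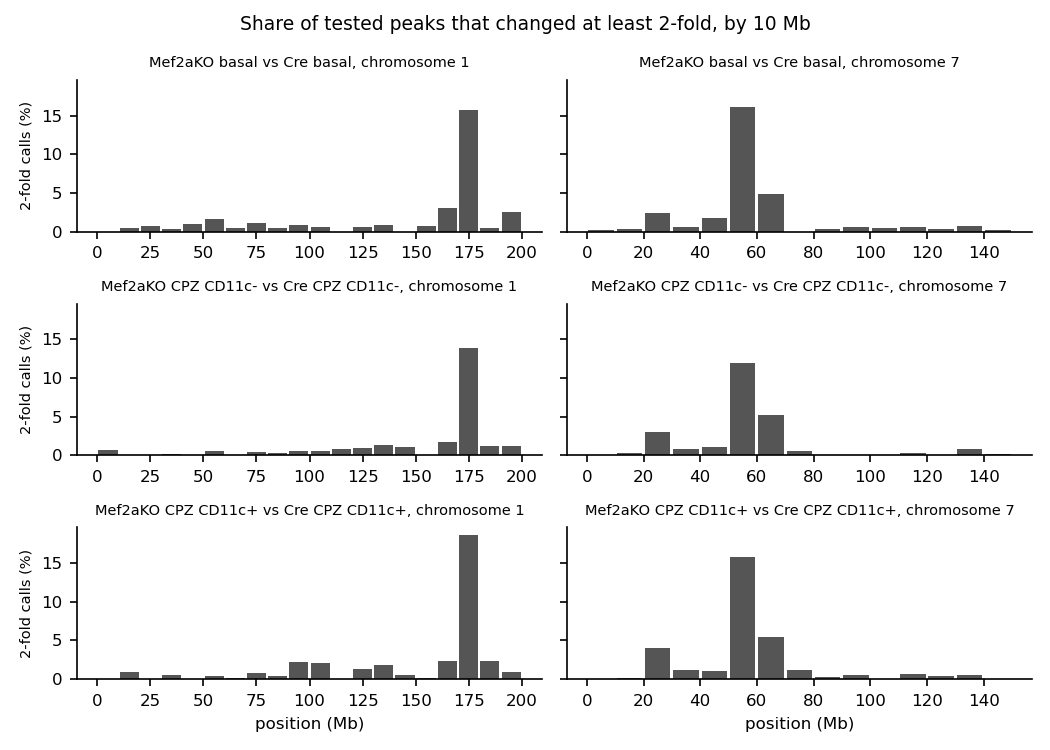
Share of tested peaks that differed by at least 2-fold between Mef2aKO and Cre cells (vertical axis, percent) in bins of 10 Mb along chromosomes 1 and 7 (horizontal axis, Mb), in 3 comparisons. The bin from 170 to 180 Mb of chromosome 1 held 15.7% in basal, 13.9% in CD11c-negative and 18.7% in CD11c-positive cells.

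After 5 weeks of cuprizone, Mef2aKO CD11c-positive cells (n = 3) were compared with Cre cells of the same gate (n = 4). The peak 114 kb from E030018B13Rik stood at 36.5 ± 2.28 against 0.122 ± 0.118 CPM (log2 8.29 ± 0.24). Higher peaks lay at Ppox, an enzyme of heme synthesis (11.9 ± 1.82 against 0.608 ± 0.234 CPM), and Blvrb (11.7 ± 0.836 against 0.642 ± 0.119 CPM). So did peaks at Prpf18 (13.9 ± 1.24 against 1.06 ± 0.478 CPM) and Kcnj9, a potassium channel (16.2 ± 1.39 against 3.28 ± 0.37 CPM). A peak in an intron of Sipa1l3 fell from 15.3 ± 1.74 to 0.673 ± 0.564 CPM (log2 -4.36 ± 0.24). Intronic peaks of Ddr2, a collagen receptor, fell from 9.29 ± 1.29 to 1.10 ± 0.245 CPM and of Cyfip1 from 12.1 ± 1.34 to 1.90 ± 0.692 CPM. A peak near Zfp974 fell from 13.2 ± 1.14 to 0.748 ± 0.411 CPM, and a peak at the start of Ifi204, an interferon-induced DNA sensor, from 7.74 ± 2.50 to 1.28 ± 0.687 CPM. Of the 2-fold differences 229 lay in the segment of chromosome 1, 112 in that of chromosome 7 and 879 on the other chromosomes. The peaks of E030018B13Rik, Ppox, Blvrb, Kcnj9, Sipa1l3, Ddr2, Cyfip1, Zfp974 and Ifi204 lie in these segments.

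In these cells 1 rose, 14 fell and 15 did not pass of 30 disease-associated genes. They had 2 higher and 43 lower of 633 peaks (adjusted p = 8.26e-08, up to 0.0245 over alternatives). A peak 41.6 kb from Mamdc2 fell 4.84-fold (1.71 ± 0.184 against 8.17 ± 1.89 CPM), the Atp6v0d2 promoter 2.74-fold (3.11 ± 0.446 against 8.35 ± 1.95 CPM), a distal Igf1 peak 1.99-fold and Cd9 1.91-fold. Of 21 integrin and matrix genes 1 rose, 5 fell and 15 did not pass (adjusted p = 0.681), with the Mmp12 promoter 2.12-fold, Itga5 1.67-fold and a peak 7.77 kb from Itgax 4.37-fold lower. Of 26 cholesterol and lipid genes 0 rose, 3 fell, 1 moved both ways and 22 did not pass (adjusted p = 0.681), with Lpl 1.93-fold lower. Of 16 Mef2, Sall and Smad genes 1 rose, 5 fell and 10 did not pass (adjusted p = 0.681), with a Klf4 peak 2.99-fold lower, and Runx1 was 1.82-fold lower. Of 25 homeostatic genes 2 rose, 3 fell, 1 moved both ways and 19 did not pass (adjusted p = 0.681). Tgfb2, a TGF-beta ligand, was 2.46-fold lower. Without the PE150 libraries the call was lost for Igf1 (log2 -0.85), Itgax (log2 -1.89), Lpl (log2 -0.79) and Tgfb2 (log2 -1.15), and without Mef2aKO CD11c-positive replicate 1 for Itga5 (log2 -0.69) and Runx1 (log2 -0.85). Without Mef2aKO replicate 3 it was lost for Itga5 (log2 -0.73) and Tgfb2 (log2 -0.98), and without Cre replicate 2 for Runx1 (log2 -0.78). None of the lists of other cell types passed (lowest adjusted p = 0.187). In all, 2525 of 163482 peaks passed, 609 higher and 1916 lower, and 331 higher and 1018 lower by at least 2-fold. The count was 1590 with DESeq2, 1652 with PE150 in the title as a covariate, and 1052 without the PE150 libraries, all Cre. It was 1611 in a fit without chromosomes 1 and 7, and 1371 and 1359 without Mef2aKO CD11c-positive replicates 1 and 3 in turn.

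In the CD11c-negative gate Mef2aKO cells (n = 2) differed from Cre cells (n = 3) at 1401 of 163482 peaks, 341 higher and 1060 lower, and 257 higher and 604 lower by at least 2-fold. The E030018B13Rik peak stood at 32.1 ± 0.553 against 0.0427 ± 0.0372 CPM. Blvrb (10.1 ± 1.38 against 0.274 ± 0.0361 CPM), Ppox (11.6 ± 0.495 against 0.714 ± 0.303 CPM) and Prpf18 (log2 4.19 ± 0.26) were higher. Sipa1l3 (0.899 ± 0.248 against 16.9 ± 2.72 CPM, log2 -4.18 ± 0.28) and Zfp974 (1.49 ± 0.935 against 13.7 ± 1.32 CPM) were lower. So were Ddr2 (0.975 ± 0.648 against 8.81 ± 0.853 CPM) and Ifi204 (1.30 ± 0.384 against 7.95 ± 1.95 CPM). All but Prpf18 lie in the segments of chromosomes 1 and 7. The disease-associated list had 2 higher and 22 lower of 633 peaks, 2 rose, 7 fell and 21 did not pass of 30 genes (adjusted p = 0.00413, adjusted p = 0.121 with an estimated correlation, 0.000471 to 0.121 over alternatives, lost without Mef2aKO CD11c-negative replicate 1 at 0.0794, 2 and 28 adjusted over the list alone). Mamdc2 (bin with 2.87%) fell 5.36-fold (1.57 ± 1 against 7.88 ± 0.636 CPM), the Atp6v0d2 promoter 4.60-fold and an Igf1 peak 1.84-fold. Cholesterol and lipid genes had 1 higher and 2 lower of 419 peaks (adjusted p = 0.9). Integrin and matrix genes had 1 higher and 3 lower of 338 peaks (adjusted p = 0.9), with the Mmp12 promoter 2.76-fold lower. The Mef2, Sall and Smad list had 1 higher and 4 lower of 681 peaks (adjusted p = 0.9), with Klf4 2.92-fold lower. Without Mef2aKO CD11c-negative replicate 2 the call was lost for Atp6v0d2 (log2 -2.02), and without Mef2aKO CD11c-negative replicate 1 for Igf1 (log2 -0.68) and Mmp12 (log2 -1.13). Lymphocyte markers were higher as a set with 0 higher and 0 lower of 53 peaks (adjusted p = 0.0362, adjusted p = 0.134 with an estimated correlation, 0.016 to 0.429 over alternatives, lost without Cre CD11c-negative replicate 2 at 0.149 and Mef2aKO CD11c-negative replicates 1 and 2 at 0.251 and 0.0723). The count of peaks was 738 with DESeq2, 2236 in a fit of both groups alone and 682 with the PE150 covariate. It was 814 in a fit without chromosomes 1 and 7, and leaving out the PE150 libraries leaves 1 Cre library. Leaving out 1 library gave 2123, 924 and 643 without Cre CD11c-negative replicates 1, 2 and 3 in turn and 397 and 430 without Mef2aKO CD11c-negative replicates 1 and 2 in turn. Column sums alone gave 392 higher and 697 lower, and header totals 302 higher and 2344 lower.

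The basal and cuprizone libraries are different samples. Outside chromosomes 1 and 7, 52 peaks were higher and 228 lower in Mef2aKO in both basal and CD11c-positive cells (by chance 1.78 and 8.97). In opposite directions 0 passed. With CD11c-negative cells the counts were 30 and 164 (by chance 0.812 and 6.64). DNA differing between the mouse lines, also in dense bins, would recur too, so this is no test of Mef2a. The interaction of genotype with CD11c had 0 peaks by edgeR and DESeq2, and unadjusted 6061 and 3053, fewer than chance gives. Header totals moved its median by 0.12 (log2). In basal Mef2aKO mice CD229-positive cells (n = 2) differed from CD229-negative cells (n = 2) at 15 of 126958 peaks, 7 higher and 8 lower. Higher were an intronic Cd36 peak at 7.89 ± 1.43 against 3.86 ± 0.597 CPM and a peak 121 kb from Cxcr4, a chemokine receptor, at 9.10 ± 1.50 against 4.82 ± 0.883 CPM. A peak near Tmem196 (4.23 ± 0.144 against 9.53 ± 2.93 CPM) was lower. With DESeq2 the call was lost for Cd36 (log2 1.03), Cxcr4 (log2 0.91) and Tmem196 (log2 -1.17), and without basal Mef2aKO CD229-negative replicate 2 for Cd36 (log2 0.89). Without basal Mef2aKO CD229-positive replicate 1 the call was lost for Cd36 (log2 0.83), and without basal Mef2aKO CD229-negative replicate 1 for Cxcr4 (log2 0.74) and Tmem196 (log2 -0.81). Without basal Mef2aKO CD229-positive replicate 2 the call was lost for Cxcr4 (log2 0.74). DESeq2 called 0 there, a fit with replicate blocks 32, and 8318 of 126958 had an unadjusted p under 0.05 by edgeR. Header totals gave 16 higher and 11 lower. Leaving out 1 library gave 7 without basal Mef2aKO CD229-negative replicate 1 and 6 and 6 without basal Mef2aKO CD229-positive replicates 1 and 2 in turn.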

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

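Chosen only after the result was seen were the interaction for CD229-negative cells and the tests of a donor segment, copy number and sequencing mode on chromosomes 1 and 7, of signal over background and of admixture. The results of this paragraph stand out because an interaction term passed between Trem2KO and WT. The change from basal to CD229-positive CD11c-negative cells differed at 20619 peaks. The list of disease-associated genes had a lower change in Trem2KO (adjusted p = 0.00559, adjusted p = 0.274 with an estimated correlation, 0.000524 to 0.274 over alternatives), as did endothelial markers (adjusted p = 0.0429, adjusted p = 0.0517 with an estimated correlation, 0.00291 to 0.151 over alternatives, lost without basal WT replicate 2 at 0.0538, basal Trem2KO replicates 1 and 2 at 0.107 and 0.0732 and Trem2KO CD229-positive replicate 1 at 0.0686). The Rtf2 peak went from 11.6 ± 1.11 to 1.60 ± 0.229 CPM in WT and 18.3 ± 1.64 to 14.6 ± 0.376 in Trem2KO, difference 2.54 ± 0.22. The others were Emg1 (2.46 ± 0.29), Fosb (2.38 ± 0.29), Irs4 (2.31 ± 0.32), Rfc5 (-6.98 ± 1.79), Postn (-4.47 ± 1.38), Etl4 (-4.44 ± 1.31) and Iqsec1 (-4.10 ± 1.21). The change in CD229-negative cells differed at 1547 peaks, 1162 higher and 385 lower. This balance turned round with column sums (78 higher and 381 lower), cyclic loess (34 higher and 159 lower) and header totals (21 higher and 68 lower). The count was 2803 with DESeq2, 887 with RLE factors, 591 at a minimum count of 30, 172 in a fit of the groups alone and 439 without the R2 libraries. The peaks included Fosb (15.7 ± 3.32 to 4.01 ± 0.749 CPM in WT and 9.04 ± 2.63 to 7.14 ± 1.08 in Trem2KO, difference 1.61 ± 0.24), Klhl25 (-3.43 ± 0.76) and Mdm2 (-2.86 ± 0.56). Without basal Trem2KO replicate 2 the call was lost for Rfc5 (log2 -3.12), Postn (log2 -4.08), Etl4 (log2 -4.59) and Iqsec1 (log2 -3.94), and without basal Trem2KO replicate 1 for Postn (log2 -4.70), Etl4 (log2 -4.27) and Iqsec1 (log2 -4.18). For the second term the same held for 2 peaks. Without basal Trem2KO replicate 1 the call was lost for Klhl25 (log2 -3.49) and Mdm2 (log2 -2.89), and without basal Trem2KO replicate 2 for Klhl25 (log2 -3.34) and Mdm2 (log2 -2.81). The first count was 12702 and 13360 without basal Trem2KO replicates 1 and 2 in turn. The second was 1014 and 539 without Trem2KO CD229-negative replicates 1 and 3 in turn, 31 and 307 without basal Trem2KO replicates 1 and 2 in turn, 1000 and 2790 without WT CD229-negative replicates 2 and 3 in turn and 1008 and 648 without basal WT replicates 2 and 3 in turn. In 34 sets of values no library stood far from its group, but only the 2 Cre groups with 4 libraries, not compared here, were tested.

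The 2-fold differences between Mef2aKO and Cre lay close together on chromosome 1 (170 to 180 Mb, with Ly9) and chromosome 7 (20 to 70 Mb, with Mef2a, 16.1% of basal peaks from 50 to 60 Mb), and less densely in other bins, among them chromosome 9 (110 to 120 Mb, 2.95% or more), 19 (20 to 30 Mb, 2.87% and 3.89% after cuprizone), 2 (0 to 10 Mb, 3.47% in CD11c-positive cells) and 16 (40 to 50 Mb, 4.51% in basal cells). A change in copy number would move all peaks of a segment one way, whereas of the 3 median log2 changes over the chromosome 1 segment the farthest from 0 was -0.0618. Sequencing mode is argued against by 168 such peaks in the basal comparison, which has no PE150 library. A stretch of DNA from another strain or donor remains open, since the share of such peaks on the chromosome 1 segment, at least 24.6 times that on other chromosomes, comes from a segment chosen for its many differences and decides nothing. An effect of Mef2a on genes that lie there stays open as well and was not tested.

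Trem2KO CD229-positive cells were lower at peaks gained in WT CD11c-positive cells under cuprizone. Signal over background stays open, since TMM centres peaks that did not respond in WT (median log2 -0.12 at 10000 draws from them, -0.91 if gained). Trem2KO had more tags in peaks. The libraries with an R2 suffix are argued against by 52649 peaks without them. Admixed cells with the basal profile would bring gained and lost peaks to the same share of the WT change, and stay open, since the shares of 39.1% ± 1.29% and 52.9% ± 2.36% (SD, n = 3) with TMM were 43.9% ± 1.49% and 50.8% ± 3.71% with header totals, 6.87 points apart and within 2 SD. A part of the response that needs Trem2 stays open as well and was not tested.

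Peaks near disease-associated genes were lower as a set in Mef2aKO CD11c-positive cells after cuprizone (adjusted p = 8.26e-08, up to 0.0245 over alternatives). In CD11c-negative cells the call was less firm (adjusted p = 0.00413, 0.000471 to 0.121 over alternatives, lost without Mef2aKO CD11c-negative replicate 1). Sequencing mode is argued against by a mean log2 change of -0.17 in CD11c-positive cells without the PE150 libraries, and the segments of chromosomes 1 and 7, though not other dense bins such as that of chromosome 19, by -0.23 without both chromosomes. An effect of Mef2a and a difference between the donor mice could each give such a set, and neither was tested.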

How the results depend on the processing

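Left out after the results were seen were chromosomes 1 and 7, and the Trem2 interaction in CD229-negative cells with its alternatives was added then. Of 337 counts of peaks under alternatives 236 were within 1.5 times the count of the report and 101 were not. For those, the cause was not tested unless the alternative tests fewer peaks or libraries. Main counts stand in the report.

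A minimum of 2-fold, which asks for more than the main call, gave 9982 (WT CD229-negative against basal), 41960 (WT CD229-positive against basal), 41471 (WT CD11c-positive against basal), 20081 (WT CD229-positive against negative), 2535 (WT CD11c-positive against negative), 8 (basal Trem2KO), 4990 (Trem2KO CD229-negative), 21377 (Trem2KO CD229-positive), 7269 (Trem2 interaction in CD229-positive), 588 (CD229-negative within Trem2KO), 16124 (CD229-positive within Trem2KO), 7088 (CD229 within Trem2KO), 1161 (basal Mef2aKO), 6 (CD229 within basal Mef2aKO), 861 (Mef2aKO CD11c-negative), 1349 (Mef2aKO CD11c-positive), 1332 (CD11c within Cre) and 360 (Trem2 interaction in CD229-negative). With DESeq2 the counts were 2429 (WT CD11c-positive against negative), 8312 (Trem2KO CD229-negative), 610 (CD229-negative within Trem2KO), 15815 (CD229 within Trem2KO), 1149 (basal Mef2aKO), 0 (CD229 within basal Mef2aKO), 738 (Mef2aKO CD11c-negative), 1590 (Mef2aKO CD11c-positive), 1818 (CD11c within Cre) and 2803 (Trem2 interaction in CD229-negative). Cyclic loess offsets gave 15642 (WT CD229-negative against basal), 5741 (Trem2KO CD229-negative), 38243 (Trem2KO CD229-positive), 9143 (Trem2 interaction in CD229-positive) and 193 (Trem2 interaction in CD229-negative), and the header totals 17 (basal Trem2KO), 9661 (Trem2KO CD229-negative), 636 (CD229-negative within Trem2KO), 27 (CD229 within basal Mef2aKO), 2646 (Mef2aKO CD11c-negative) and 89 (Trem2 interaction in CD229-negative). A fit of the compared groups alone, with fewer libraries, gave 18823 (WT CD229-negative against basal), 178 (basal Trem2KO), 4270 (Trem2KO CD229-negative), 2236 (Mef2aKO CD11c-negative) and 172 (Trem2 interaction in CD229-negative). Without R2 libraries, so with fewer samples, the counts were 7670 (Trem2KO CD229-negative), 9917 (CD229 within Trem2KO) and 439 (Trem2 interaction in CD229-negative). Replicate blocks gave 1591 (basal Mef2aKO) and 32 (CD229 within basal Mef2aKO). PE150 as a covariate gave 682 (Mef2aKO CD11c-negative) and 1652 (Mef2aKO CD11c-positive), and its libraries left out 448 (Mef2aKO CD11c-negative), 1052 (Mef2aKO CD11c-positive) and 141 (CD11c within Cre). Without chromosomes 1 and 7, so with fewer peaks, there were 814 (Mef2aKO CD11c-negative) and 1611 (Mef2aKO CD11c-positive). Column sums gave 459 (Trem2 interaction in CD229-negative), RLE factors 887 (Trem2 interaction in CD229-negative) and a minimum count of 30 591 (Trem2 interaction in CD229-negative).

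Leaving out each library in turn gave ranges of 3075 to 7059 (WT CD11c-positive against negative), 0 to 18 (basal Trem2KO), 9105 to 13546 (Trem2KO CD229-negative), 12702 to 20475 (Trem2 interaction in CD229-positive), 121 to 748 (CD229-negative within Trem2KO), 18663 to 34295 (CD229-positive within Trem2KO), 15882 to 20020 (CD229 within Trem2KO), 1112 to 3321 (basal Mef2aKO), 6 to 18 (CD229 within basal Mef2aKO), 397 to 2123 (Mef2aKO CD11c-negative), 1359 to 3092 (Mef2aKO CD11c-positive), 1297 to 3831 (CD11c within Cre) and 31 to 2790 (Trem2 interaction in CD229-negative). Where 1 library of a group was left, it is assumed to vary like the other groups. In the other comparisons all such counts were within 1.5 times.

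Of 1584 list results 1416 kept their direction and side of the threshold, 167 no longer passed, 33 of them of 83 with the estimated correlation and 65 of 500 without 1 library, and 1 reversed: neuronal markers in basal Mef2aKO, limited to peaks within 100 kb (adjusted p = 0.843, range 0.00347 to 0.843). The number of gene list tests that passed was 83, and 142 with fry. The peak sets per library overlapped by 91.8%, 86.1% (reciprocal 50%) and 94.1% (better-scoring 50%). The Trem2KO slope and the Ly9 level moved by less than their SD. Of 3706 results of the named peaks, with the 17 taken out of the text for lost calls, 3542 kept their direction and call, 163 no longer passed and 0 reversed, and 1 passed that had not. GC offsets and blocks with GC offsets were not run, as no genome sequence was at hand. Of 1.5-fold changes among 200 simulated ones, in counts otherwise nearly without group effects, 43.3% to 53.7% were found, and depth was not varied.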

Other observations

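Promoters were more common among the lower than the higher peaks in these comparisons of WT cells. In CD229-negative against basal WT cells 51.5% of the lower peaks were promoters and 3.94% of the higher ones, against 14.5% of all peaks tested. Of the peaks that were lower and higher by at least 2-fold 9.66% and 3.18% were promoters. In CD229-positive CD11c-negative against basal cells the shares were 27.4% and 5.91%, and in CD229-positive against CD229-negative cells 25.7% and 6.08%. At 2-fold or more these were 11.7% and 4.34%, and 5.18% and 3.69%, all below the share of the peaks tested. Between CD11c-positive and CD11c-negative cells the order was the reverse, with 5.71% and 9.06%.

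In Trem2KO against WT the promoters lay on the other side. In CD229-positive CD11c-negative cells 31.8% of the peaks higher in Trem2KO and 6.09% of the lower ones were promoters, and in CD229-negative cells 45.1% and 4.34%, against 13.6% of the peaks tested. Among peaks that differed by at least 2-fold this contrast was gone, with 4.32% and 4.07% in CD229-positive and 4.27% and 3.32% in CD229-negative cells. The share of tags in peaks moved along with the promoters, at 32.9% ± 1.22% in basal WT, 27.9% ± 2.40% in WT CD229-positive and 33.1% ± 0.379% in Trem2KO CD229-positive cells, so signal over background stays open for these shares. These shares rest on the same WT libraries as those of the WT comparisons.

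The libraries of the 10 comparisons with at least 3 in each group were also split in every other way into groups of the same sizes, and the compared groups were fitted alone. A comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05, with 1 split, the real one, calling as many peaks. The highest other count was 0 in each. Against basal WT cells the real counts were 18823 (CD229-negative), 84664 (CD229-positive CD11c-negative) and 83683 (CD11c-positive). They were 44671 for CD229-positive against CD229-negative and 9414 for CD11c-positive against CD11c-negative WT cells. For Trem2KO they were 4270 against WT in CD229-negative cells, 60865 in CD229-positive cells and 29553 between these subsets. With 35 splits the real and highest other count were 2150 and 1478 for Mef2aKO against Cre CD11c-positive cells. They were 2929 and 518 for CD11c-positive against CD11c-negative Cre cells, with 313 in the split by PE150. Only the real split called as many, under 0.05 uncorrected but not corrected for 10 comparisons, so chance stays open.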
